A study of Homo sapiens with 4 samples.

How the data were processed

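The samples were 4 RNA-seq libraries from MCF-7-TNR cells. Per the labels' protocols, cells grown in DMEM with serum were transfected with control or HOTAIR siRNA by RNAiMAX, a lipid reagent, total RNA was taken with TRIzol before the cells were fully confluent, and libraries were made with a stranded total RNA kit that removes ribosomal RNA. The siRNA named in the labels defined 2 groups, CTLsi and HOTAIRsi, of 2 libraries each. The siRNA sequence is not given in the sources used here.

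The authors deposited one gene table per library. Per the file headers these are RSEM gene-level results, and per the submitters' processing notes RSEM was used with the hg19 (GRCh37) build; the RSEM version, the aligner and the strand setting are not given in the sources used here. Per the file headers each table lists 27968 genes by symbol with RefSeq transcript accessions, and the deposited expected counts are RSEM's estimated counts of reads per gene, not normalized, which need not be whole numbers because reads shared by several transcripts are split between them. The deposited TPM values are transcript abundances as RSEM scales them within a library, corrected for each gene's effective length. The deposited effective length is another column of the same tables. The tables carry no coordinates. Expected counts decide most results below, so genes with near-identical copies, and genes that overlap on opposite strands, have uncertain values. Of the 77 named genes found in GENCODE v29, 47 overlap a gene on the opposite strand.

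Expected counts were rounded to whole numbers. Summed counts per library were 13362710 to 24201039, and 17355 to 18529 genes had at least 1 count. Ribosomal RNA genes took 2.74%, 1.79%, 1.71% and 1.69% of the counts in CTLsi replicates 1 and 2 and HOTAIRsi replicates 1 and 2. A chi-square of the counts of 2 libraries, divided by its degrees of freedom, was 36.8 for the CTLsi pair, 6.33 for the HOTAIRsi pair and 37.03 to 78.05 between groups, so no library was a copy of another.

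Genes were filtered with filterByExpr, which left 14587 genes, and tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, a robust quasi-likelihood fit with group as the factor, and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 14.4%. Standard errors are the fold change divided by the square root of F, and confidence intervals are at 95%. CPM values are TMM-scaled. Where the CTLsi libraries together held 1 to 3 counts, the ratio of summed counts, scaled to depth, is given with its exact binomial counting interval. Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, over the 32 lists with at least 5 measured genes. Camera with an estimated correlation and fry were run beside it, and members were also adjusted over the list alone.

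Before the data were examined, the groups, the main design, the alternatives, 38 gene lists (HOX clusters, HOTAIR-responsive genes, PRC2 and LSD1 components, estrogen response and luminal identity, stress, metabolism, proliferation, and markers of other cell types) and the rule for named genes were fixed. The rule takes HOTAIR; the 10 largest increases and 10 largest decreases among genes that pass, with a mean log2 CPM of at least 1 and no overlap between the groups; the 5 smallest p in each direction; in each list described, up to 4 passing members with the smallest p or, where none pass, 2 members with the highest mean count; and ESR1, PGR, GATA3, EZH2, SUZ12, KDM1A, HOXC11, HOXC12, HOXD10, CDH1, VIM, EGFR, CDKN1A and MYC. The list of mitochondrial genome genes matched no gene in the tables.

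The alternatives were RLE size factors, no filter beyond 1 count in any library, a mean count of at least 50, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 0.5) and on log2(TPM + 0.1), offsets from each library's effective gene lengths, leaving out ribosomal and small RNA genes, the replicate number as a block, and leaving out each library in turn. Removal of a loess trend (span 0.5) on gene length or GC content, and list tests without genes that hold a 7-base site, were added after the data had been seen.

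Sites were searched in the longest annotated 3' UTR of each gene, of at least 50 bases, in GENCODE v29 (GRCh38), which gave a sequence for 13239 of the 14587 tested genes (90.8%). Each of 16018 7-base sequences held by at least 100 genes was tested by linear regression of the log2 fold change, limited to ± 2, on its presence, with the length and base composition of the 3' UTR as covariates. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for this step and for the figures.

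The edgeR test, camera and the search over 7-base sequences were tested on simulated data, and the other steps were not. In 10 simulations of HOTAIRsi against CTLsi over 14587 genes, edgeR recovered 72.8% of 2-fold and 98.2% of 4-fold changes, with 8.37% false calls on average (4.76% to 11.7%), which is above the 5% nominal rate. Camera found the shifted list in 10 of 10 simulations and called 0 of 200 unshifted lists. The simulated genes varied independently of one another, so this does not test camera on lists of correlated genes. Both simulated groups had the same spread and no GC bias, unlike the data. The search over 7-base sequences recovered the shifted sequence in 3 of 3 simulations of HOTAIRsi against CTLsi on 13239 genes.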

Results

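RNA sequencing compared MCF-7-TNR cells, a human breast cancer cell line, after transfection with a control siRNA (CTLsi) or with an siRNA against HOTAIR (HOTAIRsi). HOTAIR is a long noncoding RNA of the HOXC cluster, best known for its binding to the Polycomb repressive complex PRC2 and to the LSD1-CoREST complex. The comparison addresses which genes differ after transfection with the HOTAIR siRNA. With only this siRNA condition it cannot separate loss of HOTAIR from other effects of the siRNA. Each group held 2 libraries. The summed expected counts were 21189604 and 13362710 in CTLsi replicates 1 and 2, and 24201039 and 15534850 in HOTAIRsi replicates 1 and 2. One count was therefore worth 0.0413 to 0.0748 CPM (counts scaled to a common library size), and a gene at 0 in a library could lie at up to 3 counts, or 0.124 to 0.225 CPM. Across the 14587 genes tested, log2 CPM correlated at 0.979 between the CTLsi libraries, at 0.992 between the HOTAIRsi libraries, and at 0.954 to 0.961 between libraries of different groups. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Where a library was left out, the spread came from the pair of the other group alone. Without a CTLsi library that is the closer HOTAIRsi pair, so such p-values leave out the difference between the CTLsi libraries. Values are TMM-scaled CPM as mean ± SD with n = 2 per group unless stated otherwise.

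HOTAIR was lower in both HOTAIRsi libraries than in both CTLsi libraries. It had 324 and 147 counts in CTLsi replicates 1 and 2, and 94 and 54 counts in HOTAIRsi replicates 1 and 2. This corresponds to 13.2 ± 3.06 CPM against 3.68 ± 0.300 CPM, a 3.58-fold decrease (log2 fold change -1.84 ± 0.24 SE, 95% confidence interval of the ratio 0.189 to 0.414, edgeR adjusted p = 0.0118). In GENCODE v29 on GRCh38, HOTAIR lies on the minus strand of chromosome 12 from 53962308 to 53974956, and its 5' part overlaps HOXC11 on the plus strand (53973126 to 53977643). HOXC11 had 4.48 ± 0.827 CPM in CTLsi and 2.94 ± 0.526 CPM in HOTAIRsi and did not pass the test (log2 fold change -0.60 ± 0.27 SE, edgeR adjusted p = 0.187). Its log2 fold change was -0.76 without CTLsi replicate 2. The use of strand in the deposited counts is not given in the sources used here, so reads from the shared stretch cannot be assigned to one of these genes with certainty. HOXC12, the neighbour on the other side (53954834 to 53958956), had 0 counts in each of the 4 libraries, which allows up to 0.225 CPM in the shallowest one.

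**Figure D1:**
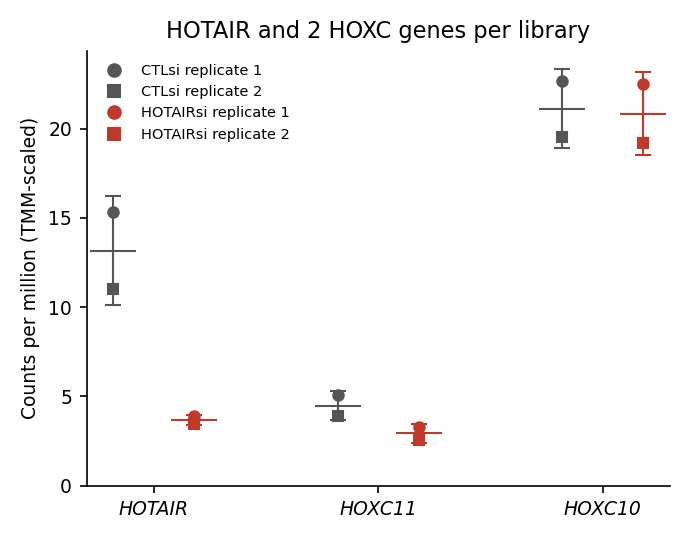
TMM-scaled CPM (vertical axis, starting at 0) of HOTAIR, its overlapping neighbour HOXC11 and HOXC10 in the same cluster; each point is a library, horizontal lines are group means and bars are ± 1 SD (n = 2). HOTAIR falls from 13.2 to 3.68 CPM with no overlap between the groups, while HOXC10 lies at 21.1 CPM in CTLsi and 20.8 CPM in HOTAIRsi.

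A total of 1302 genes changed between the groups, of which 628 were higher and 674 lower in HOTAIRsi (edgeR, Benjamini-Hochberg adjusted p below 0.05). Among them, 393 were at least 2-fold higher and 307 at least 2-fold lower. The largest increases were in genes that were nearly silent in CTLsi. SCG3, which encodes the secretory granule protein secretogranin III, rose from 0.380 ± 0.203 to 72.7 ± 0.992 CPM (log2 fold change 7.67 ± 0.28 SE, edgeR adjusted p = 0.000312). CHGB, encoding chromogranin B of dense-core vesicles, rose from 0.678 ± 0.112 to 44.5 ± 1.89 CPM, a 63.7-fold increase. NMNAT2, an NAD-synthesising enzyme of axons, had the smallest p and rose from 1.28 ± 0.0035 to 68.8 ± 0.409 CPM (53.7-fold, edgeR adjusted p = 0.000312). Genes of regulated exocytosis were among the named increases. UNC13A, a vesicle-priming factor, rose 49.9-fold to 39.0 ± 3.32 CPM, and SYT4, a synaptotagmin, rose from 0.108 ± 0.0474 to 19.9 ± 2.33 CPM. CPLX2, a complexin, had 3 counts over the CTLsi libraries together and 685 over the HOTAIRsi libraries, a depth-scaled ratio of 198 with a 95% counting interval of 67.6 to 964. The metalloproteinase gene MMP24 rose from 0.193 ± 0.0614 to 28.7 ± 0.273 CPM, and PAX5, a transcription factor of B cells, rose 54.7-fold to 14.5 ± 0.445 CPM from 7 and 2 counts in the CTLsi libraries (log2 fold change 5.77, which was 6.53 without CTLsi replicate 1). The fitted log2 fold change of CPLX2 was 6.75 without CTLsi replicate 1 and 8.30 without CTLsi replicate 2.

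The other 4 genes in the group of largest increases had 1 to 3 counts over both CTLsi libraries. CHRNB2, a nicotinic acetylcholine receptor subunit, had 1 count in CTLsi and 293 in HOTAIRsi, a ratio of 254 with a counting interval of 45.3 to 10082. GPR158, an orphan receptor, had 1 and 249 counts (ratio 216, interval 38.4 to 8573), and SST, encoding the peptide hormone somatostatin, had 1 and 182 counts (ratio 158, interval 28.01 to 6276). The microRNA host transcript MIR9-3HG had 3 and 386 counts (ratio 112, interval 37.9 to 544). The fitted log2 fold changes of CHRNB2, GPR158 and SST depended on single CTLsi libraries. Without CTLsi replicate 1 they were 6.50, 9.80 and 9.35, and without CTLsi replicate 2 they were 10.24, 6.88 and 6.43. That of MIR9-3HG moved less, between 6.60 and 6.89 with single libraries left out. These intervals of the ratios are exact binomial ones and cover counting error only. Each of these 12 increases passed the test in edgeR and kept its call when any single library was left out.

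The largest decreases were smaller in size. SERPINF1, which encodes the secreted antiangiogenic factor PEDF, fell 6.64-fold from 14.5 ± 0.741 to 2.18 ± 0.0824 CPM (log2 fold change -2.73 ± 0.20 SE, edgeR adjusted p = 0.00255). The collagen-binding receptor gene MRC2 fell 4.84-fold to 9.15 ± 0.0529 CPM, and UGP2, the enzyme that makes UDP-glucose, fell 5.16-fold from 52.2 ± 14.97 to 10.1 ± 0.850 CPM. HMGA2, a chromatin architectural protein, fell 4.43-fold from 110.6 ± 15.3 to 25.1 ± 5.16 CPM. PRDM16, RHPN1, KIAA0754, LINC01976, NPHP3-ACAD11 and BST2 completed the 10 largest decreases, at 4.04-fold to 5.90-fold. PRDM16, at the upper end, had 197 and 51 counts in the CTLsi libraries, and its log2 fold change of -2.56 was -1.75 without CTLsi replicate 1. That of NPHP3-ACAD11, -2.05, was -3.06 without HOTAIRsi replicate 1. NPHP3-ACAD11 is a read-through transcript whose counts depend on how reads were split with its parent genes, so its value is uncertain. By p, IDH1, the cytosolic isocitrate dehydrogenase (3.86-fold), the methyltransferase gene BUD23 (3.67-fold) and the ubiquitin ligase gene RNF157 (3.66-fold) ranked among the first 5 decreases, at 15.9 ± 0.0943, 25.4 ± 2.66 and 28.1 ± 3.08 CPM in HOTAIRsi. BUD23 overlaps DNAJC30 and STX1A on the opposite strand.

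**Figure D2:**
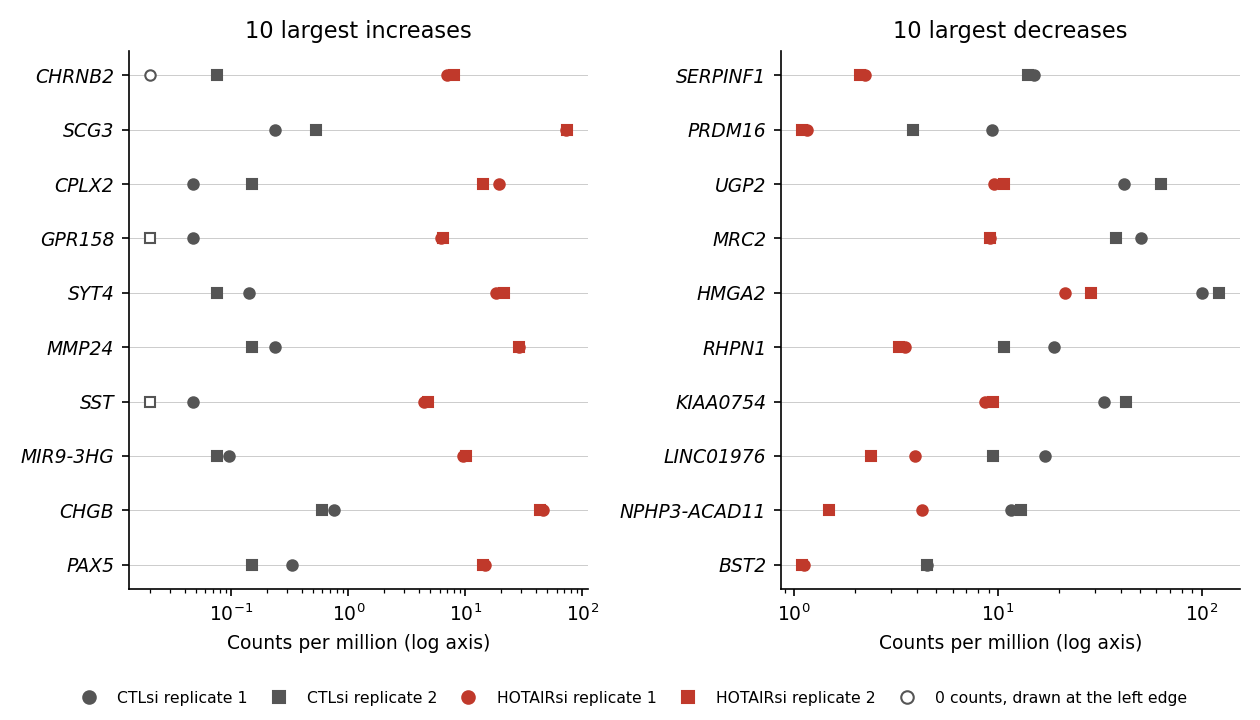
TMM-scaled CPM (horizontal log axes) of the 10 largest increases and the 10 largest decreases in each of the 4 libraries; grey points are CTLsi, red points HOTAIRsi, circles replicate 1 and squares replicate 2, and open symbols mark libraries with 0 counts, drawn at the left edge. In every gene shown both libraries of one group lie above both of the other, as the rule for these genes requires, and SCG3 moves from 0.380 to 72.7 CPM.

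A search of 16018 7-base sequences in 3' UTRs ranked CTGCAGT first among those of genes lower in HOTAIRsi, and HOTAIR holds it too. It was chosen from these same fold changes, so its excess among the fallen genes is not separate support. The 7-base sequence CTGCAGT occurs in exon 4 of HOTAIR (transcript HOTAIR-201, bases 368 to 374; GRCh38 chromosome 12, 53966329 to 53966335, minus strand). Of the 614 fallen genes with an annotated 3' UTR, 251 held it there, or 40.9%, against 20.6% of the other genes with a 3' UTR. These shares are not adjusted for the length of the 3' UTR. Among the decreases named above, the 3' UTRs of HMGA2 (3 sites), UGP2 and RNF157 (2 sites each), and BUD23, IDH1 and NPHP3-ACAD11 (1 site each) held it. The 3' UTRs of SERPINF1, MRC2, PRDM16, RHPN1 and BST2 did not, and KIAA0754 and LINC01976 had no 3' UTR that could be searched. Of the 2850 genes with the site in the 3' UTR, 251 fell (8.8%), 113 rose (4.0%) and the others did not pass. Of the 10389 genes without it, 363 fell (3.5%) and 470 rose (4.5%). Among the named genes that rose, PAX5, CDKN1A and ATF3 held it too (1 site each), so a site does not tie a single gene to a decrease.

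Targets of the tumour suppressor p53 were the gene list with the strongest shift. Of 26 measured targets, 16 rose, none fell and 10 did not pass, and the median log2 fold change was 1.05 (24 rose when adjusted over the list alone). The list was higher by camera (adjusted p = 6.16e-13), and this call was lost with an estimated correlation (camera adjusted p = 0.377). TP53I3, a p53-induced oxidoreductase, rose 12.3-fold from 1.03 ± 0.288 to 13.04 ± 0.182 CPM (edgeR adjusted p = 0.00240). The death receptor gene FAS rose 4.05-fold from 13.7 ± 2.18 to 55.1 ± 0.174 CPM, and the antiproliferative gene BTG2 rose 3.23-fold to 173.6 ± 7.30 CPM. FAS overlaps ACTA2 on the opposite strand, which had 5.13 CPM in CTLsi and 24.7 CPM in HOTAIRsi, so reads of the 2 genes may be mixed. FDXR, the mitochondrial ferredoxin reductase, rose 3.11-fold. CDKN1A, which encodes the cell-cycle inhibitor p21, rose 1.67-fold from 33.0 ± 4.89 to 55.4 ± 1.19 CPM (edgeR adjusted p = 0.0407, which was 0.256 without HOTAIRsi replicate 1 and 0.225 without HOTAIRsi replicate 2). CDKN1A also missed the threshold with limma on log2(TPM + 0.5) and log2(TPM + 0.1) (adjusted p = 0.0502 and 0.0510).

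Of 28 measured apoptosis regulators, 8 rose and 20 did not pass (9 rose when adjusted over the list alone, median log2 fold change 0.29, camera adjusted p = 0.0190). The call was lost with an estimated correlation (adjusted p = 0.450), by fry (0.0630), without CTLsi replicate 1 (camera adjusted p = 0.0529) and without CTLsi replicate 2 (0.0635). The list shares 4 genes with the p53 targets, of which 3 rose. TNFRSF10B, the TRAIL receptor DR5, rose 2.13-fold to 392.1 ± 23.7 CPM, and the BH3-only gene BIK rose from 0.678 ± 0.112 to 2.66 ± 0.0411 CPM. BAX, the mitochondrial pore-forming effector, rose 1.75-fold (edgeR adjusted p = 0.0225, which was 0.185 without HOTAIRsi replicate 1 and 0.153 without HOTAIRsi replicate 2).

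Genes of sterol and fatty acid synthesis were lower. Of 24 measured cholesterol synthesis genes and SREBP2 targets, 9 fell, none rose and 15 did not pass (14 fell and 1 rose when adjusted over the list alone, median log2 fold change -0.57, camera adjusted p = 0.000349, and adjusted p = 0.450 with an estimated correlation). IDI1, isopentenyl-diphosphate isomerase, fell 3.23-fold from 126.5 ± 4.73 to 39.2 ± 7.92 CPM (edgeR adjusted p = 0.00711). SQLE, squalene epoxidase, fell 2.13-fold to 70.8 ± 0.453 CPM. HMGCS1 and INSIG1, of the upper pathway and its feedback control, fell 1.61-fold and 1.55-fold, with edgeR adjusted p of 0.0286 and 0.0302 that became 0.318 and 0.334 without HOTAIRsi replicate 1, and 0.269 and 0.331 without HOTAIRsi replicate 2. Of 11 measured fatty acid synthesis genes, 4 fell and 7 did not pass (6 fell and 1 rose when adjusted over the list alone, median -0.44, camera adjusted p = 0.00679). That call was lost with an estimated correlation (adjusted p = 0.450) and without HOTAIRsi replicate 1 (camera adjusted p = 0.0534). The desaturase gene FADS2 fell 3.05-fold from 130.3 ± 27.9 to 42.7 ± 6.10 CPM, and ACLY, ATP citrate lyase, fell 1.65-fold from 1027 ± 18.4 to 622.5 ± 39.8 CPM (edgeR adjusted p = 0.0213, which was 0.110 without HOTAIRsi replicate 1 and 0.246 without HOTAIRsi replicate 2). The desaturase genes SCD and FADS1 fell 1.55-fold and 1.65-fold, with edgeR adjusted p of 0.0262 and 0.0263. FADS1 and FADS2 overlap each other on opposite strands, and the strand setting is not given, so their decreases may not be separate. INSIG1 and ACLY held the 7-base sequence once in the 3' UTR, whereas IDI1, SQLE, HMGCS1, FADS2, SCD and FADS1 did not.

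**Figure D3:**
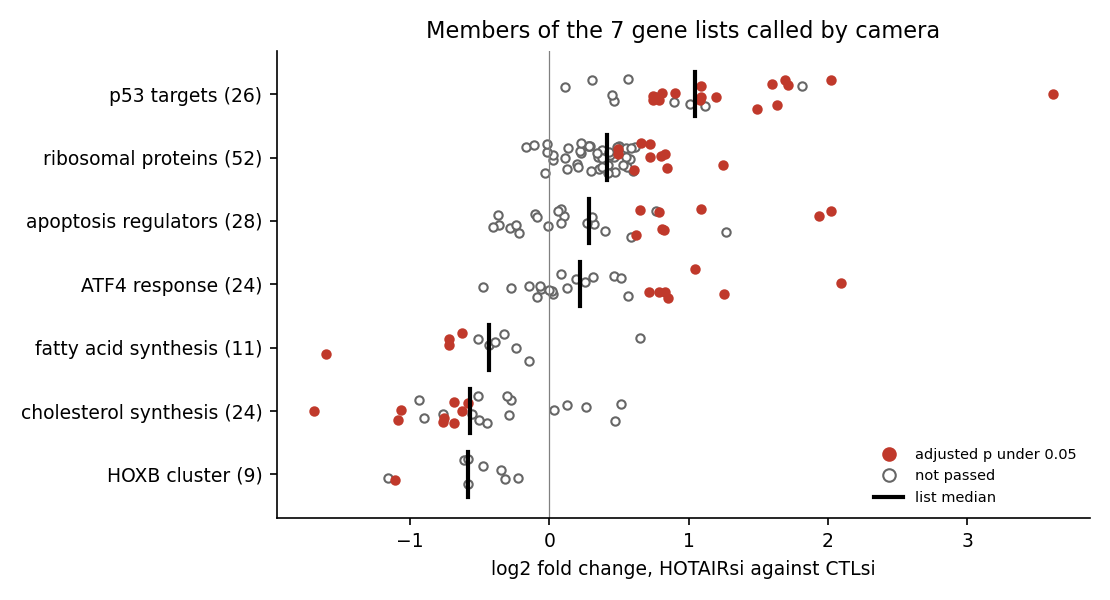
Log2 fold change of HOTAIRsi against CTLsi (horizontal axis) for each measured member of the 7 gene lists called by camera, with the number of members in brackets; filled red points passed edgeR's adjusted p of 0.05, open points did not, and vertical bars are list medians. The median of the p53 targets lies at 1.05 and that of the cholesterol genes at -0.57.

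Ribosomal protein genes were higher by a small amount. Of 52 measured, 10 rose, none fell and 42 did not pass (26 rose when adjusted over the list alone, median log2 fold change 0.41, camera adjusted p = 2.27e-07, and adjusted p = 0.377 with an estimated correlation). RPS19 rose 2.38-fold from 431.4 ± 95.9 to 1026 ± 97.6 CPM (edgeR adjusted p = 0.0161), and RPL18 rose 1.74-fold from 407.3 ± 7.27 to 708.7 ± 0.126 CPM (edgeR adjusted p = 0.0152, which was 0.0935 without HOTAIRsi replicate 1 and 0.0885 without HOTAIRsi replicate 2). RPS15 and RPS16 rose 1.80-fold and 1.58-fold; without HOTAIRsi replicate 2 their edgeR adjusted p was 0.0896 and 0.178, and without HOTAIRsi replicate 1 that of RPS16 was 0.295. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. Of 24 measured genes of the amino acid and integrated stress response driven by ATF4, 7 rose and 17 did not pass (7 when adjusted over the list alone, median 0.22, camera adjusted p = 0.0190). The call was lost with an estimated correlation (camera adjusted p = 0.450), without genes that hold the 7-base site, without CTLsi replicate 2 and without HOTAIRsi replicate 1. DDIT3, which encodes the transcription factor CHOP, rose 4.28-fold from 7.90 ± 1.74 to 33.5 ± 1.92 CPM (edgeR adjusted p = 0.00556). SLC3A2, the heavy chain of amino acid transporters, rose 2.38-fold, and the stress-induced factor ATF3 rose 2.06-fold to 83.7 ± 3.36 CPM. SLC7A5, the light chain paired with SLC3A2, rose 1.78-fold to 205.0 ± 12.8 CPM (edgeR adjusted p = 0.0273, which was 0.177 without HOTAIRsi replicate 1 and 0.0754 without HOTAIRsi replicate 2).

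In the HOX clusters, the 9 measured HOXB genes had a negative log2 fold change without exception, with a median of -0.58 (camera adjusted p = 0.00679, adjusted p = 0.574 with an estimated correlation, and fry adjusted p = 0.224), but only HOXB5 passed by itself (4 fell when adjusted over the list alone). HOXB5 fell 2.16-fold from 10.9 ± 1.29 to 5.04 ± 0.0450 CPM (edgeR adjusted p = 0.0252, which was 0.156 without HOTAIRsi replicate 1 and 0.144 without HOTAIRsi replicate 2). HOXD10, reported in earlier work as repressed by HOTAIR, fell 1.80-fold from 33.7 ± 1.39 to 18.8 ± 0.712 CPM (log2 fold change -0.85 ± 0.15 SE, edgeR adjusted p = 0.0243, which was 0.225 without HOTAIRsi replicate 1 and 0.179 without HOTAIRsi replicate 2). It was the only one of 8 measured HOXD genes to pass (camera adjusted p = 0.149). None of the 8 measured HOXC genes other than HOTAIR passed (camera adjusted p = 0.387). HOXC10, the most abundant of them, had 21.1 ± 2.21 CPM in CTLsi and 20.8 ± 2.32 CPM in HOTAIRsi. HOXC4 had 20.6 ± 3.19 and 17.4 ± 0.289 CPM (edgeR adjusted p = 0.373). The log2 fold change of HOXC4, -0.25, was -0.40 without CTLsi replicate 2. Of 11 HOXA genes, 1 rose and 1 fell (camera adjusted p = 0.708).

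Genes reported to respond to HOTAIR overexpression in breast cancer cells did not move as a group in the opposite sense. Of 4 measured genes from the list reported as repressed, 2 fell, HOXD10 and JAM2 (1.86-fold, 14.04 ± 0.484 to 7.54 ± 0.223 CPM, edgeR adjusted p = 0.0301, which was 0.223 without HOTAIRsi replicate 1 and 0.292 without HOTAIRsi replicate 2), and none rose. JAM2 held the 7-base sequence once in the 3' UTR. Of the 4 reported as induced, none passed, and ABL2 had 110.6 ± 20.1 CPM in CTLsi and 94.8 ± 5.18 CPM in HOTAIRsi, while SNAI1 had 1.78 ± 1.03 and 3.41 ± 0.0979 CPM. Without CTLsi replicate 1 the log2 fold changes of ABL2 and SNAI1 were -0.40 and 1.69, against -0.22 and 0.88 with all libraries. Both lists held too few genes for the list test.

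Among 16 measured components of PRC2 and the LSD1-CoREST-REST complex, JARID2 fell and 15 did not pass (2 fell when adjusted over the list alone, camera adjusted p = 0.332). HMG20B and RCOR2, partners of REST outside this list that were looked at afterwards, fell too (edgeR adjusted p = 0.0133 and 0.0374). JARID2, a PRC2 accessory subunit whose 3' UTR held the 7-base sequence 2 times, fell 2.44-fold from 48.0 ± 0.375 to 19.6 ± 0.235 CPM (edgeR adjusted p = 0.00791). EZH2, the PRC2 methyltransferase, had 97.4 ± 10.9 CPM in CTLsi and 64.9 ± 3.26 CPM in HOTAIRsi. It missed the threshold (log2 fold change -0.59 ± 0.15 SE, edgeR adjusted p = 0.0576). The log2 fold change was -0.47 without CTLsi replicate 1 and -0.69 without CTLsi replicate 2. EZH2 was lower under each of 16 alternatives and passed under 9 of them. Among these were both fits without a CTLsi library, DESeq2 (adjusted p = 0.0249), limma on log2(TPM + 0.5) (0.0312) and edgeR with the GC trend removed (0.0190). SUZ12 had 146.8 ± 16.9 and 169.0 ± 7.05 CPM, and the LSD1 gene KDM1A had 236.7 ± 21.1 and 202.9 ± 1.32 CPM, with edgeR adjusted p of 0.376 and 0.299. The log2 fold change of SUZ12, 0.20, was 0.32 without CTLsi replicate 2, and that of KDM1A, -0.22, was -0.32 without CTLsi replicate 1.

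Luminal and estrogen-related genes showed no shared shift. Many luminal markers were scarcely expressed in these cells, with 10 of 18 at a mean below 1 CPM over the 4 libraries. ESR1, the estrogen receptor gene, was close to the detection limit and rose from 0.244 ± 0.0779 to 1.13 ± 0.131 CPM (4.67-fold, edgeR adjusted p = 0.0339, which was 0.0794 without HOTAIRsi replicate 2). ESR1 also missed the threshold with DESeq2 (adjusted p = 0.147) and with limma on log2(TPM + 0.5) (0.115) and log2(TPM + 0.1) (0.0855), where its log2 fold change was 0.49 and 1.19. The progesterone receptor gene PGR had 8.45 ± 1.71 CPM in CTLsi and 10.5 ± 1.499 CPM in HOTAIRsi, and GATA3 had 12.7 ± 6.32 and 15.3 ± 4.33 CPM. Neither of them passed (edgeR adjusted p = 0.381 and 0.670). The log2 fold change of PGR was 0.52 without CTLsi replicate 2. That of GATA3 was 0.91 without CTLsi replicate 1 and -0.14 without CTLsi replicate 2. Of 9 measured luminal genes, ESR1 rose, ERBB2 fell (1.57-fold, edgeR adjusted p = 0.0475) and 7 did not pass (camera adjusted p = 0.708). Adjusted over the list alone, 3 luminal genes rose and 2 fell. Of 28 measured genes of the estrogen response, 3 rose and 2 fell (median log2 fold change -0.02 but mean 0.10, camera adjusted p = 0.942). ELOVL2, a fatty acid elongase, rose 1.77-fold to 56.5 ± 0.622 CPM and OLFM1, a secreted glycoprotein gene, rose from 0.605 ± 0.750 to 6.001 ± 0.231 CPM (24 and 1 counts in the CTLsi libraries; log2 fold change 3.11, which was 6.19 without CTLsi replicate 1 and 2.39 without CTLsi replicate 2), while the cadherin gene CELSR2 fell 1.68-fold to 62.7 ± 3.87 CPM and the MYB-family gene MYBL1 fell 1.88-fold. Without HOTAIRsi replicate 1 the edgeR adjusted p of ELOVL2, CELSR2 and MYBL1 was 0.158, 0.183 and 0.411, and without HOTAIRsi replicate 2 it was 0.184, 0.336 and 0.0894. With a mean count of at least 50, MYBL1 and ERBB2 missed the threshold (edgeR adjusted p = 0.0514 and 0.0515).

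The growth factor receptor gene EGFR, with 3 copies of the 7-base sequence in its 3' UTR, fell 1.72-fold from 36.6 ± 1.83 to 21.3 ± 0.433 CPM (edgeR adjusted p = 0.0285, which was 0.227 without HOTAIRsi replicate 1 and 0.297 without HOTAIRsi replicate 2). The E-cadherin gene CDH1 (6.74 ± 1.70 and 5.89 ± 0.482 CPM), VIM (689.8 ± 95.5 and 513.8 ± 31.1 CPM) and MYC (244.7 ± 58.9 and 227.4 ± 31.3 CPM) did not pass, with edgeR adjusted p of 0.593, 0.107 and 0.752. Without CTLsi replicate 2 the log2 fold changes of CDH1, VIM and MYC were -0.44, -0.56 and -0.33. Without CTLsi replicate 1 they were 0.073, -0.28 and 0.16. VIM passed under 5 of 16 alternatives. Among these were both fits without a CTLsi library, edgeR with no filter beyond 1 count (adjusted p = 0.0419) and edgeR with the GC trend removed (0.0450). Of 22 measured interferon-stimulated genes, 3 rose and 2 fell (5 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.309). HERC5 rose 2.12-fold to 65.6 ± 5.36 CPM and OAS3 rose from 0.637 ± 0.371 to 2.69 ± 0.353 CPM, whereas BST2 fell 4.04-fold and IFIT1 fell 1.97-fold to 4.96 ± 0.162 CPM. HERC5 lost its call without HOTAIRsi replicate 2 (edgeR adjusted p = 0.0572). OAS3 lost it without HOTAIRsi replicate 1 (edgeR adjusted p = 0.0540) and on log2(TPM + 0.1) (limma adjusted p = 0.0555), and its log2 fold change of 1.99 was 2.83 without CTLsi replicate 1. IFIT1 lost it without HOTAIRsi replicate 1 (edgeR adjusted p = 0.268) and without HOTAIRsi replicate 2 (0.228).

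The other lists were not called by camera. Of their measured members, 2 of 16 NF-kappaB targets rose (camera adjusted p = 0.0670), as did 3 of 24 lysosome and autophagy genes (0.0853) and 3 of 19 TGF-beta targets (0.0990). Of 16 YAP targets, 4 rose and 1 fell (0.123), and of 26 glycolysis and hypoxia genes, 1 rose and 3 fell (0.170). Of 20 MAPK feedback genes, 2 rose and 1 fell (0.214), and of 12 basal markers, 1 rose and 3 fell (0.387). Of 15 ERBB and MET receptors and ligands, 2 rose and 2 fell (0.971). In 13 Wnt targets, 20 mesenchymal genes and 30 respiratory chain genes, 1 gene each fell (0.309, 0.320 and 0.345). Of 13 genes of RNA interference and 28 genes of G1/S and replication, 1 rose and 1 fell in each (0.502 and 0.708), and 1 of 18 endoplasmic reticulum stress genes rose (0.739). None passed among 30 G2/M genes (0.486), 14 epithelial junction genes (0.309) and 5 protocadherin beta genes (0.281). Of the markers of other cell types, 1 of 5 measured fibroblast genes rose (0.665), and none of 2 leukocyte and 3 endothelial genes passed. The 2 measured replication-dependent histone genes did not pass either, and genes of the mitochondrial genome were not analysed here. Without CTLsi replicate 1, camera called the NF-kappaB, lysosome, TGF-beta, glycolysis and MAPK lists, with the spread taken from the HOTAIRsi pair alone.

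The count of changed genes depended on single libraries. It was 5153 without CTLsi replicate 1, 7379 without CTLsi replicate 2, 562 without HOTAIRsi replicate 1 and 510 without HOTAIRsi replicate 2. The CTLsi libraries differed more from each other than the HOTAIRsi libraries did. Fits without a CTLsi library take the spread from the HOTAIRsi pair alone, and they called the most genes. On the deposited TPM values (limma on log2(TPM + 0.5)), 426 genes were higher and 1048 lower, so that 28.9% of the changed genes were higher in HOTAIRsi, and the median log2 fold change of all genes lay at -0.12. The libraries also differed in GC bias, and with the GC trend removed edgeR called 3432 genes, of which 1442 were higher and 1990 lower.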

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

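The length trend, the GC trend and the list tests without genes that hold the 7-base site were chosen only after the data had been seen; the other alternatives were set beforehand. HOTAIR stayed lower and past the threshold under each of 16 alternatives, with log2 fold changes of -2.04 to -1.57, both from leaving out a CTLsi library. The 1302 changed genes (628 higher, 674 lower) became 2618 (1150 and 1468) with no filter beyond 1 count and 3432 (1442 and 1990) with the GC trend removed. Higher genes numbered 414 with a mean count of at least 50 and 414 on log2(TPM + 0.1). Lower genes numbered 1048 and 1022 on log2(TPM + 0.5) and log2(TPM + 0.1), and 1020 with the length trend removed. The cause was not tested. On TPM the median of all genes shifted to -0.12 and -0.13. Leaving out single libraries gave 510 to 7379 changed genes, 194 to 3682 lower and 316 to 3697 higher. Without either HOTAIRsi library only the CTLsi pair measures the spread, the lone HOTAIRsi library is assumed to vary like it, and calls were fewest. Without either CTLsi library only the closer HOTAIRsi pair measures it, calls were most, and a call kept there is little sign of stability. Of the 64 named genes that passed, 20 lost the call without HOTAIRsi replicate 1 and 22 without HOTAIRsi replicate 2, none without either CTLsi library, and at most 3 under any other alternative; 5 had no value with a mean count of at least 50, SST among them.

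The labels name no batch or day shared by libraries of the same number, so whether they share one is not known. The deviations of same-numbered libraries correlated at 0.207 across genes, and the difference of replicate 2 from replicate 1 had a GC trend of the same sign in both groups. With the replicate block, 4492 genes changed (2200 higher and 2292 lower), 1302 of them shared with the main result, and the list test called the same number of lists, 7.

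The 7 gene lists became 0 with an estimated correlation, 6 by fry (HOXB and apoptosis lost, YAP targets gained at adjusted p = 0.0270), and 9 with the GC trend removed (NF-kappaB and lysosome lists gained) or a mean count of at least 50 (NF-kappaB and TGF-beta lists gained), and 5 to 11 when single libraries were left out; the cause was not tested, though camera with an estimated correlation has only 2 residual degrees of freedom to work with. Without genes that hold the 7-base site the ATF4 list lost its call (adjusted p = 0.175; 0.00802 to 0.450 over its alternatives) and the YAP targets gained one (0.00625; 0.00625 to 0.574). Reversed directions were seen only in results that did not pass. On the log2 scale, with single libraries left out, GATA3 ranged from -0.14 to 0.91, CDH1 from -0.44 to 0.0728, MYC from -0.33 to 0.16 and HOXC10 from -0.145 to 0.0956. GATA3, CDH1 and MYC passed only at the end of their range that kept the reported direction, in fits whose spread came from the HOTAIRsi pair alone. Without genes that hold the site the direction turned for the ERBB and MET list (adjusted p = 0.876) and G1/S genes (0.833). It also turned with a single library left out for 8 lists, whose adjusted p then ranged over the left-out libraries from 0.683 to 0.956 (ERBB and MET), 0.443 to 0.798 (estrogen response), 0.443 to 0.971 (fibroblast), 0.650 to 0.971 (G1/S), 0.145 to 0.912 (G2/M), 0.443 to 0.897 (HOXA), 0.145 to 0.980 (HOXC) and 0.474 to 0.928 (endoplasmic reticulum stress). The cause was not tested. Depth limits genes near 1 CPM such as ESR1, where CTLsi replicate 2, with 13362710 counts in all, held 4 reads.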

Other observations

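The tests on the 8-base site, on other sequences of the same composition, on the REST transcript, on REST targets chosen by their CTLsi counts, on neuronal transcripts and on p53 targets were chosen only after the results had been seen, and the list of REST targets was written after the strongest changes had been seen, without the genes whose values were known. Among genes not yet described, 4 YAP targets rose. ANKRD1 went from 0.905 to 9.05 CPM, GADD45B from 7.41 to 20.8 CPM, CTGF from 4.47 to 11.9 CPM and AJUBA from 12.6 to 25.1 CPM, whereas CRIM1 fell from 53.5 to 28.2 CPM (edgeR adjusted p from 0.00454 to 0.0263); these were named after their values were seen. In the HOXA cluster, HOXA1 rose from 17.2 to 28.9 CPM and HOXA13 fell from 27.1 to 14.5 CPM (edgeR adjusted p = 0.0327 and 0.0255). Of 18 luminal markers, 10 had a mean below 1 CPM over the 4 libraries and 6 a mean above 10 CPM. Of 25 epithelial junction genes, 12 lay below 1 CPM and 8 above 10 CPM, and of 25 mesenchymal genes, 7 and 9 did. Over the 4 libraries EPCAM had a mean of 0.511 CPM, and CLDN3, GRHL2, TFF3 and AGR2 had 0. VIM, CDH2 and ZEB1 had 601.3, 97.3 and 67.9 CPM, but the epithelial genes DSP and KRT18 had 238.1 and 66.3 CPM. In CTLsi the neuronal transcripts NEFL and UCHL1 had 257.4 and 395.1 CPM, and NEFM 0.891 CPM. The labels call the cells a breast cancer line, and its identity was not tested beyond these levels. The CTLsi libraries differed from each other in a GC-dependent way, with a Spearman correlation across genes of -0.61 between GC content and the log2 difference of replicate 2 from replicate 1, against -0.37 for the HOTAIRsi pair; genes are not independent replicates.

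Genes with the 7-base sequence CTGCAGT in the 3' UTR were lower in HOTAIRsi. It had the lowest t of 16018 sequences (t = -13.5, slope -0.17 log2 units, 2850 genes), and 100 shuffles of the fold changes among genes gave none below -4.675. The tables argue against length or composition of the 3' UTR as the whole cause, since 592 other sequences of the same composition gave no t below -3.70. Sequences that hold all but the first or all but the last base of CTGCAGT were left out of these. One of those left out, TCTGCAG, had t = -4.92. The spread within a group is argued against too, since the larger absolute t between 2 libraries of one group was 1.96. Each HOTAIRsi library against each CTLsi library gave -11.8 to -14.2. A candidate explanation is off-target pairing through the seed of the HOTAIR siRNA, since HOTAIR holds the sequence, followed by an A. Genes with the sequence and that A had a median log2 fold change that differed by -0.0921 from that of genes with the 7 bases alone (bootstrap interval -0.139 to -0.0287, permutation p = 0.0002 over genes). This comparison is not separate support, because TGCAGTA, the end of the sequence with that A, ranked 2nd in the same search (t = -11.6). It was also not adjusted for the length of the 3' UTR or the number of sites, and genes are not independent replicates. The siRNA sequence would settle whether the seed pairs with this sequence. An RNA of HOTAIR's length holds a given 7-base sequence by chance in 13.7% of cases, and the 8 bases in 3.62%. An effect of HOTAIR loss itself on such genes, for example through a microRNA, was not tested.

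Of the increases named above, SCG3, CHGB, SST, SYT4, CPLX2 and UNC13A encode parts of regulated secretion. CHRNB2, MMP24, PAX5, GPR158, MIR9-3HG and NMNAT2 do not. CHRNB2 had the largest fitted value, which rests on 1 count over both CTLsi libraries. UNC13A and NMNAT2 were named by p, and no list of secretory genes was fixed or tested. A hypothesis is relief from REST, the repressor of neuronal genes: of 33 REST targets whose values had not been seen, 17 passed the expression filter, which admits a target silent in CTLsi only if it rose; 9 rose and 1 fell, their median log2 fold change of 0.997 lay above each of 10000 random lists matched on expression (99th percentile 0.321), and the 13 targets with at least 10 counts in both CTLsi libraries, of which 6 rose and 1 fell, had a median of 0.930 (99th percentile 0.322, matched on CTLsi expression). Whether REST itself fell cannot be told apart from no change, since its log2 fold change was -0.405 (95% interval -1.145 to 0.336, edgeR adjusted p = 0.421; its 3' UTR holds the 7-base sequence once) and the CTLsi libraries lay at 31.5 and 61.5 CPM. Of 12 genes of REST, its partners and PRC2, 3 fell (HMG20B, RCOR2 and JARID2) and 9 did not pass, among them RCOR1, HDAC1, HDAC2, SIN3A and EHMT2 (edgeR adjusted p = 0.879, 0.431, 0.768, 0.105 and 0.122); HMG20B fell from 64.0 and 48.4 to 21.0 and 22.6 CPM and RCOR2 from 18.5 and 16.8 to 10.4 and 10.1 CPM (edgeR adjusted p = 0.0133 and 0.0374), without the sequence in their 3' UTR. Neuronal cells in the HOTAIRsi libraries stay open too, because only 5 abundant neuronal transcripts were low enough in CTLsi to tell, with a median of 0.380 and members that moved apart (CRMP1 6.30 to 23.8 CPM, which passed, NEFM 0.891 to 2.30, GAP43 10.4 to 13.6, TUBB3 8.88 to 9.26 and MAP2 4.48 to 2.38 CPM), and 2 of the other 9 fell (TUBA1A 428.2 to 167.8 and TUBB2B 146.3 to 72.7 CPM); an effect through HOTAIR's binding of LSD1-CoREST was not tested.

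The p53 targets rose with 16 of 26 members past the threshold. Expression level, gene length and GC content are argued against as the whole cause, since the list's median lay at percentile 100 of 10000 random lists matched on these (99th percentile 0.187 against 1.05). The lowest list median over the scalings was 0.870, on log2(TPM + 0.5). These scalings moved the median of all genes no further than -0.13, on log2(TPM + 0.1). A list median of 1.05 could not have vanished under them, so the check covers only scaling shifts of that size. Without genes that hold the 7-base site the list kept its call, which was lost with an estimated correlation (camera adjusted p = 0.377). Loss of HOTAIR and a response to unintended targets of the siRNA may both raise p53 targets, and a second siRNA against HOTAIR, which would separate them, was not analysed here.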
